A study of Arabidopsis thaliana with 4 samples.

How the data were processed

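Rosette leaves of Arabidopsis thaliana, accession Col-5, were profiled on 4 Affymetrix arrays, 1 array for each combination of nutrient solution and time. Per the labels, plants grown on agar were moved to hydroponics under constant light and received either a full nutrient solution with 0.25 mM phosphate or a solution without phosphate, in which extra potassium sulphate replaced the potassium. Leaves were sampled 4 h or 100 h after nutrient removal. The solution of each array was taken from its treatment label and the time from its age label. The array titles also carry short codes that these labels do not explain: NPK for full nutrients at 4 h, PO6 for no phosphate at 4 h, P24 for full nutrients at 100 h and P72 for no phosphate at 100 h. The numbers in the codes differ from the labelled hours, and the array labelled full nutrients at 100 h has a code of the kind borne by both no-phosphate arrays. The labels were followed as written, and the alternative in which the 4 h full-nutrient array serves as the control at 100 h was fixed before the data were examined.

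Per the labels, total RNA was extracted with a column kit, copied into biotin-labelled cRNA and hybridised, and the scanner background of each array is recorded. The values deposited by the authors are linear intensities, 1 per probe set, on each of the 4 arrays. The software, background correction and summary method behind these intensities are not given in the sources used here. Every array of 8297 probe sets had a mean intensity of 100.2 after 2% of the values at each end were trimmed, so the arrays had been scaled alike before deposit, and no further scaling was applied in the main setting. Because the scaling equalises the mean of every array, a change in the total amount of mRNA per cell cannot be seen.

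Of the 8297 probe sets, 50 controls were left out and 8247 were analysed. The platform annotation listed 3864 of them. Of these, 3794 named 1 gene and 70 named several genes and were left unnamed, while 4383 probe sets were not listed and have no name here. Through gene identifiers, 3784 probe sets were matched to 3592 loci of the RefSeq gene table, which follows the TAIR10.1 assembly and was used for names only. No coordinates are given, because the source files name no genome build.

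Intensities under 7.25, the mean over arrays of the 30th percentile, were set to that floor, and log2 values were taken. A level of 22.45, the mean over arrays of the median, served as the filter on dim probe sets. Pairs of arrays were compared by a rule of size: a probe set was called higher or lower where the ratio was 2-fold or more and the brighter array was at or above the level. With 1 array per group there is no replicate check and no p-value for these 4 comparisons (phosphate at 100 h, phosphate at 4 h, time in full nutrients and time without phosphate). Each array enters 2 of the 4 ratios, so the ratios are not independent. A ratio to an array at the floor is a bound. The error of measurement on an array was estimated from 91 genes with 193 probe sets, as the spread of the log2 ratio between probe sets of the same gene. It covers neither the spread between plants nor that between hybridisations. Some of these probe sets have consecutive numbers and may share probes. That would make the estimate, and the share of calls it predicts in each of the 4 comparisons, too low. Probe sets of a gene are given separately where they disagree and were averaged on the log2 scale for gene lists.

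An additive model of time and phosphate was fitted to all 4 arrays with limma's lmFit and eBayes, over the 4756 probe sets whose highest array reached the level. The test was two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The model leaves 1 residual degree of freedom, to which eBayes added 4.20 prior degrees of freedom. That residual holds the interaction of phosphate and time as well as chance, so the test asks whether an effect is large against its own disagreement between the 2 levels of the other factor. A second fit of this kind, added after the data were seen, held time and the difference of the phosphate effects between the times, with the phosphate effect over both times left in the residual. The labels do not say how many plants or cultures an array represents, and p-values measure only the spread between these arrays.

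Gene lists were fixed before the data were examined: 22 lists with 359 genes, of which 25 genes had a named probe set. For a list with at least 3 measured genes, the median log2 ratio was placed among 10000 random lists of the same size, drawn from 1879 genes and matched on mean level in 20 bins. The percentile describes these arrays only. The genes named in the text were chosen by a rule set at the same time. It takes the 10 largest ratios in each direction for each phosphate comparison and the 5 largest for each time comparison, among probe sets above the floor on both arrays that name 1 gene. It adds up to 10 genes with the smallest adjusted p in the additive fit, all measured phosphate-list genes, and the 3 members of each other list farthest from 0.

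The calculations were tested on simulated data made from the 4756 real probe sets, with known changes added. For phosphate at 100 h, the size rule recovered 83% of changes of 1.5 and 90% of changes of 3.0 on the log2 scale and called 3.16% of unchanged probe sets. At 4 h the shares were 84%, 91% and 2.61%. The decreases of 3.0 that were missed, 10 of 50 at 100 h and 9 of 50 at 4 h, had all reached the floor, and no increase of 3.0 was missed. For phosphate over both times, limma recovered 95% of changes at either size, and 4.04% of its calls were unchanged probe sets. The simulated arrays carried a normal measurement error alone, with the SD of a log2 ratio pooled over the 4 comparisons (0.46, larger than the 0.43 and 0.38 of the 2 phosphate comparisons, and expected to call 2.96%), and no interaction of phosphate and time, so this share does not hold for the real arrays, where the smallest called time difference was 2.28. Of unchanged lists of 8 genes, 5% fell outside the central 95% of random lists.

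The alternatives tried were quantile normalization, cyclic loess, no floor, a floor at the 45th percentile, no filter on level, averaging the probe sets of a gene, the other control array at 100 h, an intensity trend in eBayes and random lists not matched on level. Scaling to the 9 spike-in probe sets, a correlation and counts over bright probe sets, the other control array for the calls shared by the 2 times, and quantile normalization and spike-in scaling for the count of probe sets far below the other arrays were added after the data were seen. Versions were R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.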

Results

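Gene expression in Arabidopsis rosette leaves was measured after phosphate was withdrawn from hydroponic plants. The series title states the question, which genes respond to phosphate deficiency. The 4 arrays form a square of 2 solutions, full nutrients and no phosphate, by 2 times, 4 h and 100 h, with 1 array at each corner. No value below has a replicate, and the number of arrays limits the precision of every comparison. The solution and time of each array follow its labels, although the title codes leave the array labelled full nutrients at 100 h in doubt. That array enters the phosphate ratios at 100 h, the time ratios in full nutrients and the additive fit.

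The arrays differed in technical measures that moved with the solution. The mean scanner background was 49.74 on the full-nutrient and 56.94 on the no-phosphate array at 4 h, and 55.21 and 69.92 at 100 h. The 9 spike-in probe sets, which report RNA added to every hybridisation, were lower on the no-phosphate array by a mean log2 ratio of -0.51 ± 0.12 (SD over probe sets) at 4 h and -1.06 ± 0.24 at 100 h. The ratio of 3' to 5' signal for GAPDH, a sign of RNA or labelling quality, was 4.07 with full nutrients and 2.61 without phosphate at 4 h, and 4.52 and 2.12 at 100 h. For ubiquitin it was 3.09, 2.57, 3.35 and 2.97 in the same order. Across 4756 probe sets, arrays of the same time correlated best, with r = 0.944 at 4 h and 0.946 at 100 h, against 0.897 for the 2 full-nutrient arrays and 0.813 for the 2 no-phosphate arrays. No phosphate at 4 h with full nutrients at 100 h had 0.883, and full nutrients at 4 h with no phosphate at 100 h had 0.852. The 2 no-phosphate arrays were thus the least alike of all pairs. These correlations run across probe sets, which are not independent replicates. The SD of a log2 ratio from measurement on an array was 0.43 for phosphate at 100 h, 0.38 for phosphate at 4 h, 0.48 for time in full nutrients and 0.54 for time without phosphate.

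After 100 h, leaves without phosphate had lower signal than full-nutrient leaves for a chitinase gene, a peroxidase gene, a glucosinolate enzyme gene and a sugar transporter gene, among others. The chitinase gene AT2G43590 was at an intensity of 117.1 with full nutrients and 9.20 without phosphate, a log2 ratio of -3.67, and its second probe set went from 309.4 to below the floor. The peroxidase gene AT2G18150 was at 131.8 and 25.9 (log2 ratio -2.35), and Hsp70-2, a cytosolic chaperone of the HSP70 class, at 46.0 and 11.5 on 1 probe set, while its other probe set was at the floor on both 100 h arrays. AOP3, which encodes a dioxygenase of glucosinolate synthesis, was at 1120 with full nutrients and below the floor without phosphate, at least 154-fold lower. SAG29, the sucrose transporter SWEET15 and a senescence marker, was at 38.6 and below the floor, at least 5.32-fold lower.

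Genes with higher signal without phosphate at 100 h included AT1G09390, a GDSL-type lipase or esterase gene, at 9.70 and 50.9 (log2 ratio 2.39). AT2G33220, which encodes a subunit of mitochondrial complex I, was at 121.5 and 549.0 (2.18), the lectin-like gene AT1G78820 at 65.5 and 281.9 (2.11), and AT1G76960 at 799.9 and 3367 (2.07). The aspartyl protease gene AT3G52500 had a log2 ratio of 1.89 and TBL45, of a family that acetylates cell wall polysaccharides, 1.83. The remaining genes that the naming rule took were AT1G65190 (4.91-fold), AT2G05790 (2.15), AT4G01590 (1.95) and AT4G11100 (1.94) on the higher side. On the lower side they were AT4G29030 (-2.68), AT2G07000 (-2.46), AT1G65500 (-2.30), AT2G32210 (-2.09), the RNA helicase gene AT2G33730 (-2.08), AT2G44581 (-1.96) and AT1G05340 (-1.94). Of the genes lower at 100 h, AOP3, SAG29, AT1G65500, AT2G32210, AT2G33730 and Hsp70-2 were at least 4-fold below all 3 other arrays. So was the second probe set of AT2G43590. A local blemish may account for some of them. With the floor at the 45th percentile, AT4G11100 (0.95) and AT2G44581 (-0.84) fell under 2-fold, and AT4G01590 had 1.05. Other dim genes shrank but stayed at 2-fold or more, as AT1G09390 (1.55), AT1G65190 (1.40), Hsp70-2 (-1.41) and AT2G33730 (-1.10).

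By the size rule, 206 probe sets were higher and 233 lower without phosphate at 100 h, of 4331 with a bright enough array. That is 10.1% of them, where a normal error with this comparison's measurement SD would give 2.00%, which is too low if probe sets of a gene share probes. In a simulation with the SD pooled over the 4 comparisons, 3.16% of all unchanged probe sets were called. Those too dim to be tested counted there as not called. With the 4 h full-nutrient array as the control, as the title codes leave possible, the counts were 442 and 697, AT2G18150 turned from lower to higher, with a log2 ratio of 1.54, and 4 of the 20 named ratios no longer reached 2-fold: AT4G29030 (-0.05), AT3G52500 (0.51), AT4G01590 (0.58) and AT4G11100 (0.56). With arrays scaled to the spike-in probe sets, whose own ratio is lower on the no-phosphate array, the counts were 2771 higher and 44 lower, and the median log2 ratio of all probe sets moved from 0 to 0.78.

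At 4 h the leaves without phosphate showed more low than high signals. AT2G25510 was at 4438 with full nutrients and 70.1 without phosphate, 63.3-fold lower, while its intensities at 100 h were 4555 and 4452. AT1G76960 was 26.0-fold lower, at 1115 and 42.9. The peroxidase gene AT5G39580 was at 140.3 and 10.7 (log2 ratio -3.71) and BGLU28, a beta-glucosidase, at 157.7 and 22.6 (-2.80). The complex I gene AT2G33220, at 180.9 with full nutrients, was 9.94-fold lower without phosphate. CP5 had log2 ratios of -2.42 and -1.34 on its 2 probe sets. The others taken by the rule were AT4G39840 (-3.85), AT2G22510 (-3.31), AT5G49440 (-3.17) and AT4G02540 (-2.46). Apart from AT5G39580, BGLU28 and AT4G02540, these lower genes were at least 4-fold below all 3 other arrays here, CP5 on 1 probe set. A local blemish may account for some of them.

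Fewer genes were higher without phosphate at 4 h. SAG29 was at 177.7 with full nutrients and 1085 without phosphate, 6.11-fold higher, and AOP3 at 367.8 and 1706, 4.64-fold higher. The peroxidase gene AT2G18150 was at 8.90 and 65.2, 7.33-fold higher, and AT1G02300, a cathepsin B-like protease gene, at 90.0 and 306.6, 3.41-fold higher. Log2 ratios between 1.36 and 2.04 were found for AT4G01410, AT4G01810, AT1G09460, AT2G18600, AT3G52610 and AT4G36195. With the floor at the 45th percentile, AT4G01810 (0.63), AT3G52610 (0.57) and AT2G18600 (0.46) fell under 2-fold. By the size rule, 99 probe sets were higher and 298 lower, of 4478, so that 8.87% were called where a normal error with this comparison's measurement SD would give 0.806%, and the simulation with the pooled SD gave 2.61%. Scaling to the spike-in probe sets gave 734 higher and 111 lower and moved the median log2 ratio of all probe sets to 0.23.

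Genes that were low without phosphate at 4 h tended to be high without phosphate at 100 h, and the reverse. Of 4053 probe sets tested at both times, 78 were called in opposite directions, where independent lists would give 13.4, and 16 in the same direction, where they would give 15.5. Of the 78, 56 were lower at 4 h and higher at 100 h, and 22 were the reverse. Across the 4756 probe sets the log2 ratios correlated with r = -0.246 (Spearman's rho = -0.208), although the 2 ratios share no array. AT1G76960, AT2G33220, AT1G78820, AT4G01590, AT3G52500, AT4G02540 and TBL45 were lower at 4 h and higher at 100 h. AOP3, SAG29, AT2G18150, AT2G43590, AT4G29030 and AT1G02300 were higher at 4 h and lower at 100 h. For AT2G43590 this held for 1 of its 2 probe sets, while the other had 0.72 at 4 h, under 2-fold. The ratio at 100 h was at least 2-fold above that at 4 h for 640 probe sets and at least 2-fold below it for 482, of 4756. A model with both main effects and the interaction leaves no residual degree of freedom. In a fit added after the data were seen, with the phosphate effect over both times left in the residual, limma called 0 probe sets for this difference, with 468 of 4756 at an unadjusted p under 0.05 and a smallest adjusted p of 0.143. Scaling to the spike-in probe sets gave 320 in the same direction, where independent lists would give 365.8, and 99 in opposite directions, where they would give 58.7, with 1470 and 208 for the difference. With the 4 h full-nutrient array as the control at both times, which the 2 ratios then share, 100 were called in the same direction and 61 in opposite directions, 31 of them among the 78.

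**Figure D1:**
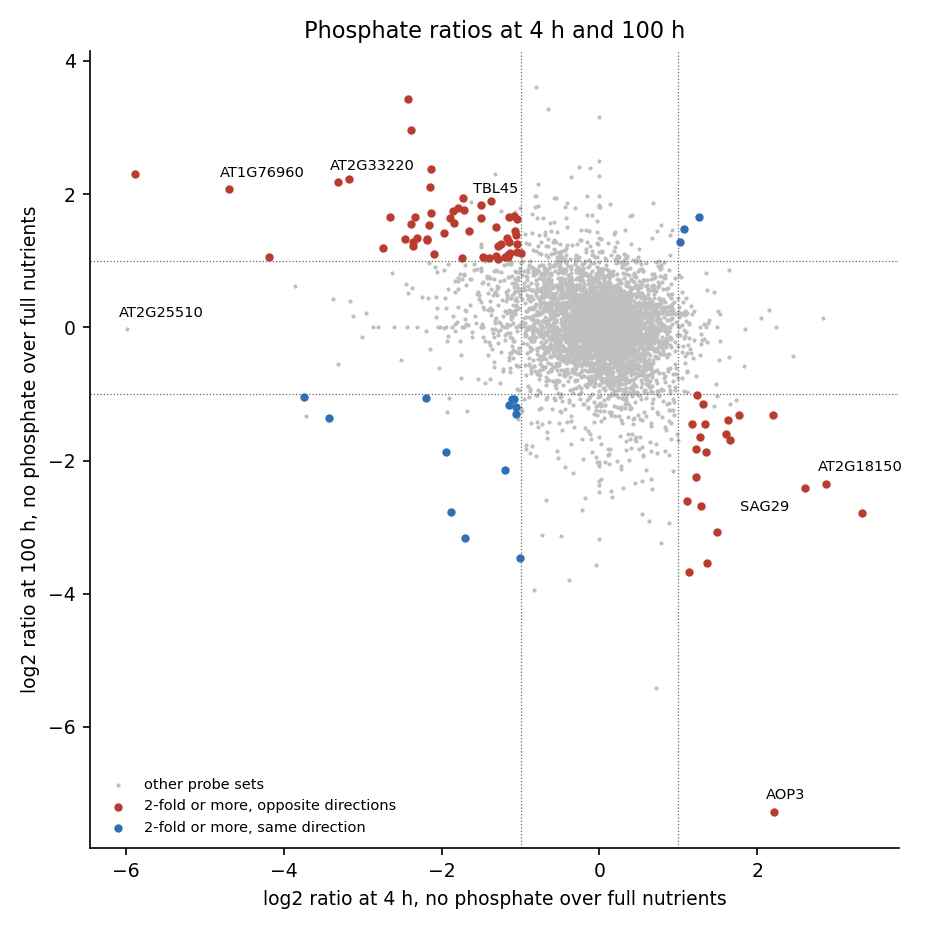
Log2 ratio of no phosphate over full nutrients at 4 h (horizontal axis) and at 100 h (vertical axis), 1 point per probe set, for the 4756 probe sets whose highest array reached the level, with dotted lines at 2-fold. The 78 red points, called at both times in opposite directions, lie in the upper left and lower right corners, and the 16 blue points were called in the same direction; ratios that involve an array at the floor are bounds.

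**Figure D2:**
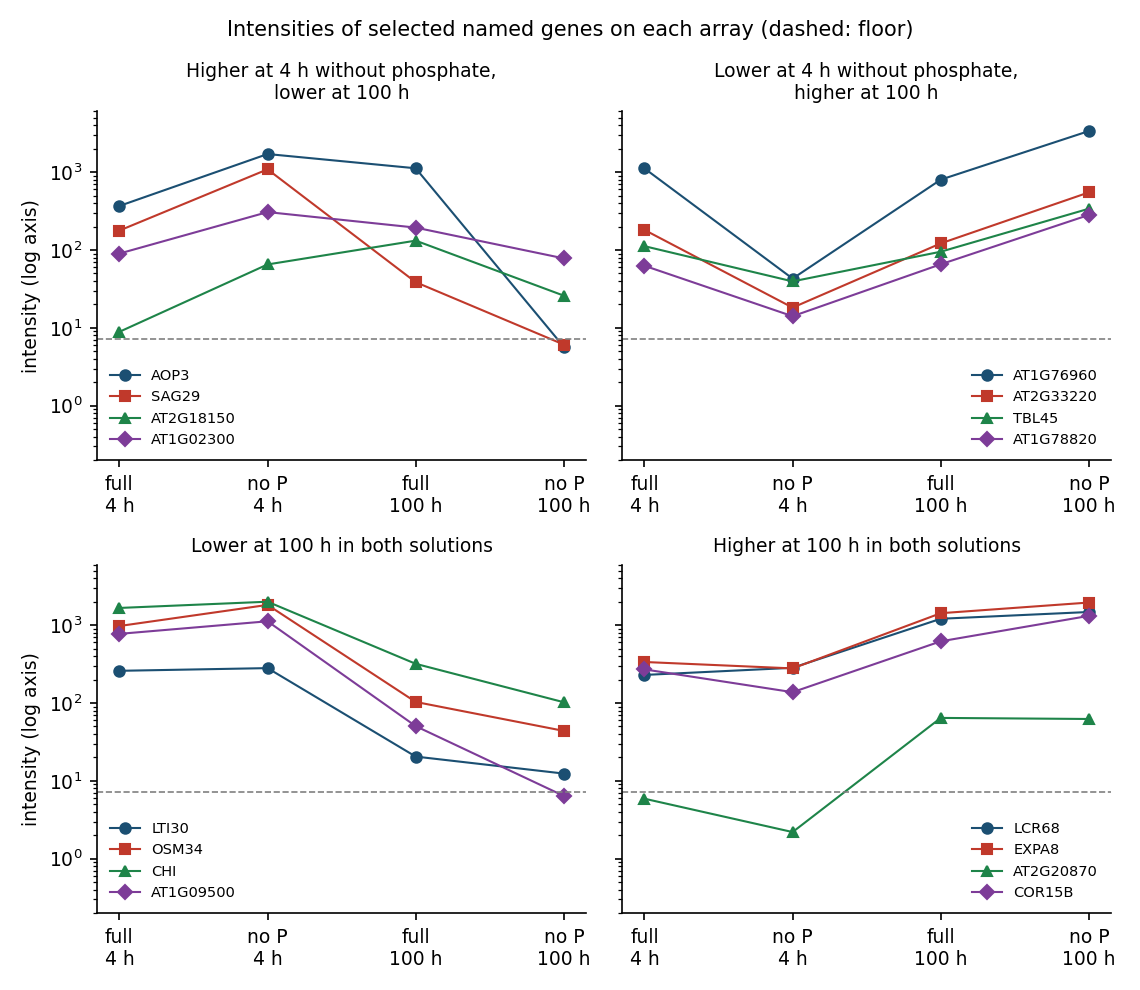
Deposited intensity (log axis) of 4 genes in each panel on the 4 arrays, 1 array per group, with the floor of 7.25 dashed; lines only join the values of a gene. AT1G76960 went from 1115 to 42.9 at 4 h and from 799.9 to 3367 at 100 h, while LTI30 was at 258.8 and 280.3 at 4 h and at 20.5 and 12.4 at 100 h.

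Leaves with full nutrients had more probe sets with lower than with higher signal at 100 h against 4 h, though not among bright probe sets. LTI30, a dehydrin induced by cold and drought, was at 258.8 at 4 h and 20.5 at 100 h, 12.6-fold lower. AT1G09500, related to cinnamyl alcohol dehydrogenase, was 15.3-fold lower, AT1G30700, of the berberine bridge enzyme family, 22.3-fold lower, AT4G39670 12.3-fold lower and AT2G17740 11.5-fold lower. On the higher side, LCR68, a defensin-like peptide gene, was at 229.1 and 1206, 5.26-fold higher. The peroxidase gene AT2G18150 was 14.8-fold higher, AT4G29030 6.16-fold higher, and the chitinase gene AT2G43590 5.09-fold and 7.26-fold higher on its 2 probe sets. By the size rule, 291 probe sets were higher and 572 lower at 100 h, of 4516, or 19.1% called where a normal error with the measurement SD would give 3.54%. Quantile normalization gave 356 and 472, and among probe sets at 100 or more on both arrays 102 were higher and 102 lower. Scaling to the spike-in probe sets gave 163 higher and 633 lower.

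Leaves without phosphate likewise had lower signal at 100 h than at 4 h for an osmotin gene, a dehydrin gene, a glucanase gene and a chitinase gene, among others. OSM34, the osmotin gene of the thaumatin family, was at 1817 at 4 h and 43.8 at 100 h, 41.5-fold lower. LTI30 was 22.6-fold lower, AT1G05340 21.3-fold, the beta-1,3-glucanase gene AT4G16260 20.3-fold and the chitinase gene CHI (AT2G43570) 19.5-fold lower. The genes with the highest ratios were those that had been low at 4 h without phosphate: AT1G76960, 78.5-fold higher at 100 h, AT2G25510, 63.5-fold, AT2G33220, 30.2-fold, AT1G78820, 20.0-fold, and AT5G49440, 19.7-fold. By the size rule, 695 probe sets were higher and 790 lower at 100 h, of 4534, or 32.8% called where a normal error with the measurement SD would give 6.43%. Among probe sets at 100 or more on both arrays 207 were higher and 146 lower, and quantile normalization gave 766 and 699. Scaling to the spike-in probe sets gave 1347 higher and 528 lower. Of 4294 probe sets tested in both solutions, 349 were lower at 100 h in both, where independent lists would give 87.2, and 119 were higher in both, where they would give 36.5. Opposite directions were found for 38, where independent lists would give 116.6, and the log2 ratios for time in the 2 solutions correlated with r = 0.561 across probe sets.

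Over both solutions, limma called 96 probe sets for time at an adjusted p under 0.05, of 4756 tested, with 90 lower and 6 higher at 100 h and a smallest adjusted p of 0.0411. LTI30 fell by 4.08 ± 0.38 (log2, SE, n = 4 arrays, limma adjusted p = 0.0443), with lower values at 100 h in both solutions. Log2 differences for time were -4.12 for AT4G39670, -4.05 for ChiC, a class V chitinase, -3.53 for AT4G01870, -3.16 for 1 probe set of the pectin methylesterase gene ATPMEPCRB, and -2.80 for AT2G34810, all called lower, as was GH3.3, which encodes an auxin-conjugating enzyme (limma adjusted p = 0.0450). AT4G20860, of the berberine bridge enzyme family, was called on both of its probe sets (-3.09 and -3.60). AT2G20870 rose by at least 3.13 on 1 probe set, below the floor on both 4 h arrays, while the other, with a log2 difference of 0.68, did not pass the test, nor did the other probe set of ATPMEPCRB (-1.73, adjusted p = 0.0805). The differences of AT4G39670, ChiC, ATPMEPCRB and AT4G20860 also rest on values at the floor and are bounds (-5.85 for 1 probe set of AT4G20860 with no floor). Of the 96 calls, 41 had an array at the floor and 32 had a gene name, 5 higher and 27 lower. In 13 of them both arrays of a time were at the floor. This sets their phosphate ratio at that time to 0 and can shrink the residual on which p rests. After quantile normalization and cyclic loess limma called 0 probe sets, with 997 and 979 at an unadjusted p under 0.05 against 1024 as reported. The 96 had nearly the same size in all 3, a median of 3.10 as reported, 3.04 and 3.11 (log2, absolute), and passed the threshold by little, with adjusted p up to 0.0497 as reported and from 0.0543 to 0.0668 and 0.0613 to 0.0752 after the 2 normalizations; LTI30 had -3.99 and -4.02. With no floor limma called 0 higher and 4 lower, with no filter on level 0 and 0, and with spike-in scaling 0 and 27, where LTI30 had adjusted p of 0.0767, 0.288 and 0.0483. With the floor at the 45th percentile limma called 89 and 276, so the number of calls depended on the floor.

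No probe set was called by limma for phosphate over both times, and the smallest adjusted p was 0.999. An unadjusted p under 0.05 was found for 89 of the 4756 probe sets, or 1.87%. Large averages over both times did not pass either, as for AT2G25510 (-3.01 ± 1.35), AT5G39580 (-2.52 ± 0.62) and AOP3 (-2.53 ± 2.11; log2, SE, n = 4 arrays, adjusted p = 0.999 each).

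Genes of photosynthesis, 8 measured of the 49 listed, were below their full-nutrient levels without phosphate at 4 h, and above their 4 h levels at 100 h in both solutions. At 4 h all 8 were below full nutrients, with a median log2 ratio of -0.58, at the 0.05 percentile of matched random lists, whose central 95% ran from -0.31 to 0.25. This median was -0.36 after quantile normalization and -0.060 after scaling to the spike-in probe sets. The random range is that of the main setting, and spike-in scaling shifts all 4 h ratios well above the floor alike. The value of -0.060 is therefore not to be set against that range. PSBW, a photosystem II subunit, had the lowest ratio (-1.13 over 2 probe sets, -1.83 and -0.43 singly), followed by LHCB4.3, a light-harvesting protein (-0.78), and PSAN, a photosystem I subunit (-0.69). At 100 h, 6 of the 8 were below full nutrients and the median was -0.16, at the 15.1 percentile, and it was 0.056 after quantile normalization and 0.90 after spike-in scaling. From 4 h to 100 h all 8 were higher in both solutions, with medians of 0.67 (percentile 99.3) in full nutrients, which was 0.39 after quantile normalization, and 1.12 (percentile 99.9) without phosphate. LHCB4.3 had a log2 ratio of 2.28 without phosphate and RCA, the activase of Rubisco, 0.16. In limma's additive fit none of the 12 probe sets of these genes passed for time, neither over all probe sets nor adjusted over the list alone, where the smallest adjusted p was 0.0622. The no-phosphate array at 4 h, on which these genes were low, also had the lower spike-in signal and GAPDH ratio of its pair.

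**Figure D3:**
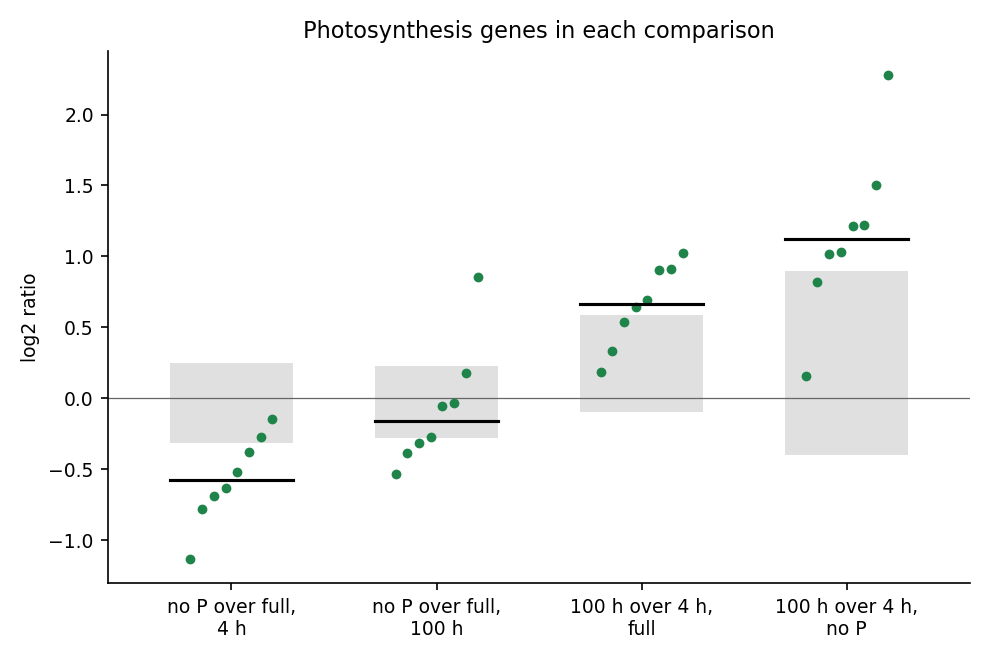
Log2 ratios of the 8 measured photosynthesis genes (points) in each of the 4 comparisons, with their median (black line) and the central 95% of medians of 10000 matched random lists (grey). All 8 points lie below 0 at 4 h without phosphate, where the median is -0.58, and above 0 for time in both solutions, while the 4 h phosphate median is -0.060 after spike-in scaling. The grey ranges are those of the main setting, and spike-in scaling shifts ratios well above the floor alike.

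The list of cold, drought and abscisic acid genes, 4 measured of 19, moved in both directions. LTI30 had log2 ratios for time of -3.66 with full nutrients and -4.50 without phosphate. COR15B, a chloroplast protein induced by cold, had 1.20 and 3.26, KIN2 had 0.27 and 1.70, and COR47, another dehydrin, had -0.49 and -1.73. The list's medians for phosphate were -0.43 at 4 h (percentile 4.17), which turned to 0.086 after spike-in scaling, and -0.04 at 100 h (percentile 34.5), which turned to 1.03, and for time -0.11 (percentile 23.9) and -0.02 (percentile 41.5). The percentiles are those of the main setting, and spike-in scaling shifts ratios well above the floor alike. In limma's fit for time, 1 of the 6 probe sets, that of LTI30, passed over all probe sets and 2 passed adjusted over the list alone.

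The other lists had at most 2 measured genes, too few for a percentile. For cell wall loosening, EXPA8, an expansin, rose by 2.45 over both solutions (limma adjusted p = 0.0487), and EXPA4 had 0.67 and did not pass. For senescence, WRKY53, a regulator of leaf senescence, was lower at 100 h (log2 ratios -1.41 and -1.63) and lower without phosphate (-0.81 at 4 h and -1.02 at 100 h, where the mean spike-in ratios were -0.51 and -1.06), while SAG29 went in opposite directions as given above. For starch, APL3, a subunit of ADP-glucose pyrophosphorylase, was higher without phosphate at both times (1.02 and 1.29), and SBE2.2, a branching enzyme, had -0.69 and 0.49. APL3 was dim, at 22.3 with full nutrients and 45.3 without phosphate at 4 h, and at 14.3 and 34.9 at 100 h. Both of its full-nutrient values lay under the level of 22.45. STZ, the zinc finger protein ZAT10 of the rapid touch and wound list, had -1.53 and -2.25 for time. GI of the circadian clock had log2 ratios for time in full nutrients of -0.76, -0.31, 0.89 and 0.40 on its 4 probe sets, the first of them under the level on all 4 arrays, and DFR of anthocyanin synthesis had 0.73 at 4 h and 0.33 at 100 h without phosphate. THI2.1, a thionin gene of the jasmonate and wounding list, was under the level as the mean of its 3 probe sets; 1 of them was below the floor with full nutrients and at 38.6 without phosphate at 100 h, at least 5.32-fold higher, and at 36.4 and 30.3 at 4 h, while the 2 others were too dim to be called. The sulphate gene APS3 had -0.69 and 0.15 for phosphate, and the small heat shock gene AT1G53540 0.07 and 0.63. Adjusted over the list alone, which for 1 or 2 probe sets corrects little, limma passed 1 of 2 probe sets of the starch list for phosphate over both times, that of APL3 (adjusted p = 0.0337 over the list and 0.999 over all probe sets). For time it passed 2 of 2 for senescence, 2 of 2 for rapid touch and wounding, 1 of 2 for cell wall loosening, and the single probe sets of AT1G53540 and WRKY6, of which EXPA8 alone passed over all probe sets.

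Of the 65 genes in the 4 phosphate lists (transport, phosphatases and nucleases, membrane lipid remodelling, and signalling), 1 had a named probe set. This was WRKY6, a repressor of the phosphate exporter gene PHO1, with intensities of 153.3 and 78.9 at 4 h and 36.3 and 40.2 at 100 h, with full nutrients and without phosphate. Its log2 ratios for phosphate were -0.96 and 0.15, under the 2-fold rule at both times. Whether the plants had entered phosphate deficiency, and whether the solution labels hold for each array, could not be checked through marker genes, since no probe set was named here for the others.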

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

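The tests on RNA quality, on a mislabelled array and of the difference between the times were chosen only after the opposite directions of the phosphate ratios had been seen.

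Removing phosphate went with opposite calls at 4 h and 100 h for 78 probe sets, and the difference between the times was not tested in a model with both main effects, since each group holds 1 array. With the phosphate effect over both times left in the residual, limma called 0 probe sets for it (468 at an unadjusted p under 0.05, smallest adjusted p 0.143). Among the named genes, the log2 ratio at 100 h minus that at 4 h was 6.77 for AT1G76960, 5.49 for AT2G33220, 4.26 for AT1G78820, 3.79 for AT4G02540, 3.68 for AT4G01590, 3.34 for TBL45 and 3.27 for AT3G52500. In the other direction it was -9.48 for AOP3, -5.22 for AT2G18150, -5.02 for SAG29, -4.80 for the 1 probe set of AT2G43590 called at both times, -3.97 for AT4G29030 and -3.08 for AT1G02300. AOP3 and SAG29 were below the floor without phosphate at 100 h and AT4G01590 at 4 h, so their differences are bounds.

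An intensity-dependent difference between arrays is argued against, because the correlation of the 2 ratios across probe sets stayed at -0.246 after cyclic loess. RNA quality may still contribute: the 3' to 5' log2 ratio shifted the same way at both times for GAPDH (-0.64 and -1.09), where opposite shifts would be needed, but the ubiquitin shifts (-0.27 and -0.18) lie within the measurement error, and the smaller product of the 2 shifts was 0.0467. A mislabelled full-nutrient array at 100 h cannot be told apart from a real reversal: with the 4 h full-nutrient array as the control, 31 of the 78 calls were left opposite, and of the 13 named genes 7 were left, AT2G18150 (1.54) was called higher at both times and AT4G29030 (-0.05), AT1G02300 (-0.21), AT3G52500 (0.51), AT4G01590 (0.58) and AT4G02540 (0.83) were no longer called at 100 h, and the correlation was 0.059, but the 2 ratios then share an array and mix time with phosphate. An exchange of solutions within a time stays open and was not tested, since only 1 phosphate-list gene had a named probe set. A reversal of the leaf response between an early and a late stage of phosphate withdrawal, and a difference between single plants or harvests, for which the design has no replicate, stay open as untested explanations. Of the 13 named genes, AT1G76960, AT2G33220 and AT1G78820 were at least 4-fold below all 3 other arrays on the 4 h no-phosphate array. AOP3 and SAG29 were so on the 100 h no-phosphate array, and the probe sets given for the others were not. A local blemish, taken up below for such probe sets, stays open for these genes.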

How the results depend on the processing

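Scaling to the spike-in probe sets, the correlation over bright probe sets and the other control array for the calls shared by the 2 times were chosen only after the data were seen. The cause of each change below was not tested, except where the setting's own construction gives it. No paired analysis was possible because each group holds 1 array, beyond the additive fit itself, which compares the solutions within each time, and leaving out an array was not possible either, since the additive fit would keep 0 residual degrees of freedom. For time over both solutions, limma called 6 higher and 90 lower as reported, 0 and 0 with quantile normalization, with cyclic loess and with no filter, 0 and 4 with no floor, 89 and 276 with the floor at the 45th percentile, 12 and 150 with an intensity trend, and 0 and 27 with spike-in scaling. The 96 calls kept their direction in the first 2 of these, with a median size of 3.04 and 3.11 against 3.10 (log2) and a median SE of 0.363 and 0.366 against 0.367; the prior degrees of freedom fell from 4.201 to 3.978 and 3.800, which raises p. For phosphate over both times it called 0 in every setting. With no filter, which tests more dim probe sets, 357 were lower for phosphate at 100 h and 150 higher at 4 h, and 29 were called in the same direction at both times. With the 4 h full-nutrient array as the control at 100 h, 442 were higher and 697 lower, the photosynthesis median was 0.56, AT2G18150 reversed to 1.54, AT4G29030 (-0.05), AT3G52500 (0.51), AT4G01590 (0.58) and AT4G11100 (0.56) were under 2-fold, 100 were called in the same direction at both times, and the correlation of the phosphate ratios was 0.059. Spike-in scaling shifts the ratio of 2 arrays well above the floor by a constant, and ratios at or near the floor by less. It gave 2771 higher and 44 lower at 100 h, 734 and 111 at 4 h, 163 higher for time in full nutrients and 1347 without phosphate. The difference of the phosphate ratios was higher for 1470 and lower for 208, and 320 were called in the same direction at both times. The photosynthesis medians became 0.90 for phosphate at 100 h, -0.060 at 4 h and 1.52 for time without phosphate, and the cold, drought and abscisic acid medians 1.03 and 0.086 for phosphate at 100 h and 4 h. Quantile normalization moved the photosynthesis medians to 0.056 and -0.36 for phosphate at 100 h and 4 h and to 0.39 for time in full nutrients, which cyclic loess also moved to 0.39. In the other settings the correlation of the phosphate ratios at 4 h and 100 h ranged from -0.256, over probe sets at 100 or more on all arrays, to -0.208 with no filter. The 78 opposite calls ranged from 60 to 101. Between 27.8% and 31.5% of the probe sets on an array were at or under the floor, which limits ratios of dim probe sets to bounds. With the floor at the 45th percentile, some named phosphate ratios fell under 2-fold. These were AT4G01810 (0.63), AT3G52610 (0.57) and AT2G18600 (0.46) at 4 h, and AT4G11100 (0.95) and AT2G44581 (-0.84) at 100 h.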

Other observations

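The gene families below, the check of other probe sets of a gene, the scalings of the count of probe sets far below the other arrays, the tests on the lean towards lower signal at 100 h and the remaining way to part the arrays were chosen only after the data were seen.

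Gene families were formed from symbols that share a prefix, with at least 4 measured genes, which gave 7 families and 28 medians over the 4 comparisons. All percentiles are those of the main setting. Spike-in scaling shifts the ratios of a comparison alike where both arrays are well above the floor, so its medians are not to be set against them. The TBL family, whose members acetylate cell wall polysaccharides, was lower without phosphate at 4 h in all 5 measured genes, with a median log2 ratio of -1.39 at the 0.05 percentile of matched random lists. It was -1.23 after quantile normalization, -1.33 after cyclic loess and -0.87 after spike-in scaling, and 4 of the 5 were at least 2-fold lower as reported, but after spike-in scaling none was and 1 lay above 0. TBL24 had -1.40, TBL26 -1.39 and TBL37 -1.07. At 100 h all 5 ratios lay above 0, 1 of them at 2-fold (TBL45), with a median of 0.73 at the 99.1 percentile, and 0.72, 0.70 and 1.80 in the 3 other scalings. The 6 WRKY transcription factor genes had a median of -0.88 for phosphate at 4 h (percentile 0.55) and -1.33 for time in full nutrients (percentile 0.3), which were -0.37 and -1.48 after spike-in scaling, as in WRKY22 with -1.02 and -1.24.

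The 4 beta-glucosidase genes of the BGLU family were lower at 100 h than at 4 h in both solutions, with medians of -2.12 (percentile 0.05) in full nutrients and -1.62 (percentile 0.340) without phosphate. In the 3 other scalings only 3 of these genes were measured, all below 0. BGLU28 and BGLU46 were at the floor on both 100 h arrays, and BGLU15 on the one without phosphate. Their ratios to those arrays, and so the medians, rest on bounds. BGLU15 had -2.57 and a bound of -4.07, BGLU25 -0.50 and -1.61. The 5 ATG8 genes of autophagy were all above full nutrients at 4 h without phosphate, with a median of 0.42 (percentile 97.4), and none reached 2-fold; after spike-in scaling the median was 0.93 and 2 reached it. The 4 serine carboxypeptidase-like genes had a median of 0.66 at 4 h (percentile 99.6), with 3 of 4 above 0. It was 1.17 after spike-in scaling, which takes the mean spike-in log2 ratio of -0.51 out of every 4 h ratio well above the floor. The 10 UDP-glycosyltransferase genes had a median of -0.38 at 4 h (percentile 1.12), which turned to 0.13 after spike-in scaling, and the 4 aldehyde dehydrogenase genes one of 0.41 (percentile 93.4), which was 0.92 after it, with ALDH7B4 at -3.17 for time without phosphate. With 28 medians examined, some beyond the central 95% may arise by chance. The medians given with a percentile for TBL, WRKY, BGLU, the serine carboxypeptidase-like and the UDP-glycosyltransferase genes lay outside it. Those of the ATG8 and aldehyde dehydrogenase genes lay inside it.

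Probe sets at least 4-fold below all 3 other arrays were found 22 times on the 4 h and 29 times on the 100 h array without phosphate, but 3 times on the 4 h and 1 time on the 100 h full-nutrient array. Probe sets at least 4-fold above all 3 others ran the other way, with 9 and 11 on the full-nutrient arrays at 4 h and 100 h and 2 and 7 on the no-phosphate arrays. The low ones included AT2G25510 (70.1 against 4438, 4555 and 4452) and AOP3 (5.70 against 367.8, 1706 and 1120), and at 100 h the peroxidase genes AT2G38380 and AT5G64120. Among the named genes they also held, at 4 h, AT1G76960, AT2G33220, AT4G39840, AT2G22510, AT5G49440 and 1 probe set each of AT1G78820 and CP5. At 100 h they held SAG29, AT1G65500, AT2G32210, AT2G33730, AT1G09500 and 1 probe set each of Hsp70-2 and AT2G43590. Between-array scaling may account for part and cannot be told apart from a real difference: the no-phosphate arrays held 10.6 times as many after cyclic loess, which cannot show an offset common to all probe sets, but 2.44 times as many after spike-in scaling, with 22 of the 51 left. A local blemish on the array may account for some: 44 of the 51 had no other probe set to compare. For 5 genes another probe set was also low, by 1.04 to 3.54 on the log2 scale, but in 3 of them the probe sets have consecutive numbers and may share probes, and the other 2 genes, AT1G09500 and CP5, had a median shortfall of 1.95, too few to decide.

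More probe sets were lower than higher at 100 h than at 4 h. Between-array scaling as the whole cause is argued against for the size rule in both solutions, where 2.23, 3.00 and 3.15 times as many were lower in both as higher in both after quantile normalization, cyclic loess and spike-in scaling. For the additive fit, at least 91.7% of the 96 probe sets with the smallest p were lower in 3 other scalings (93.8% as reported). That share cannot decide. The called decreases measured 2.28 to 6.09 (log2), and the mean spike-in time ratios of 0.15 in full nutrients and -0.40 without phosphate could hardly turn them. Scaling may account for the lean without phosphate alone, which turned to 47.7% lower after quantile normalization (766 higher and 699 lower) and to 28.2% after spike-in scaling. After cyclic loess it stayed at 52.6% (696 higher and 772 lower), against 53.2% as reported. Weak signal or background cannot be told apart as a cause, since among probe sets at 100 or more on all arrays 46 were lower in both and 42 higher (1.095 times), but 49 and 32, 53 and 20, and 47 and 30 after quantile normalization, cyclic loess and spike-in scaling. Growth of the leaves between the harvests, a declining response to the transfer or removal at 4 h, and differences between harvests stay open and were not tested. A mislabelled full-nutrient array at 100 h stays open too, since that array enters the time ratios in full nutrients and the additive fit. If it had received no phosphate, these would mix solution with time.

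The 4 arrays can be parted into 2 pairs in 3 ways, too few for any statement on chance. Parting by time gave limma 96 calls and 1024 probe sets at an unadjusted p under 0.05, parting by phosphate 0 and 89, and the remaining way, which sets the full-nutrient array at 4 h and the no-phosphate array at 100 h against the other pair and so tests the difference of the phosphate effects between the times, 0 and 468. The residual of the fit by phosphate holds that difference, and the residual of the remaining fit holds the phosphate effect. The counts of 89 and 468 are therefore not independent.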
